A study of Homo sapiens with 12 samples.

How the data were processed

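RNA was sequenced from SW1990 cells, a human pancreatic cancer line, after 24 h in medium without glucose. Per the labels, the cells carried wild-type PHGDH or a form with the substitution S371A or S55A. The prefix of the expressed form, rPHGDH, is not explained there, nor is it said whether the cells' own PHGDH was removed. The 12 libraries formed 4 groups of 3: WT-1 and S371A in experiment 1, WT-2 and S55A in experiment 2. The labels number the wild-type groups to match the mutant they stand beside, and each experiment has its own deposited table. Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

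The deposited counts are whole numbers of reads or fragments per gene, and the deposited FPKM values are those counts scaled by gene length and library total. Within each table, count divided by FPKM and by the column total was constant for a gene to within a relative deviation of 1.1e-05, over 12157 genes in experiment 1 and 11738 in experiment 2 with 50 or more counts in every library. The submitters' processing notes name CASAVA, HISAT2 2.0.4, StringTie 1.3.0 and edgeR, and the builds GRCh38 and mm10, without saying what each was used for. The gene coordinates in the deposited count tables are human. The counting step, the annotation release and whether strand was used are not given in the sources used here. In experiment 1, 58302 genes are listed, and in experiment 2, 50868, with 50356 shared. Of these, 97.4% have the same coordinates and 60.8% the same name in both, so the tables rest on different annotation releases. PHGDH is among the genes whose coordinates differ. Genes and lists were therefore tested within a table or through the contrast of the mutant effects. Levels were set against each other across the tables in 1 check, that of the S phase list over genes with the same coordinates. The spread of WT-2 minus WT-1 over all such genes is given beside it. Other levels given side by side were not tested against each other. Gene names are those of the experiment 1 table where it lists the gene.

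Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, libraries were scaled with TMM factors, and the robust quasi-likelihood F test was used with Benjamini-Hochberg adjustment at 0.05. S371A was compared with WT-1 and S55A with WT-2, each over its own 6 libraries. The difference of the mutant effects was tested over all 12 libraries, with each group keeping its own mean. Each mutant belongs to 1 experiment, so a difference between the mutant effects cannot be separated from a difference between the experiments or their cells. Log2 fold changes carry a standard error taken from the fold change and its F statistic, and CPM values use TMM-scaled totals and are given as mean ± SD over 3 libraries. Lists of genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 28 pathway lists with 5 or more measured members. In all, 33 lists were written before the data were examined, as were the tests and alternatives other than those said to be chosen later, and the rule for naming genes; 5 of the lists hold markers of other cell types.

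The naming rule took PHGDH, JUN, PARP1 and ATF4. It also took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM whose groups did not overlap, and for each called list the 3 members with the smallest p. For the difference it took the 5 largest values in each direction among called genes with a mean of at least 5 CPM over the 12 libraries. Clone-based names were not counted as symbols, and not every member the rule took is printed. Other genes are said to have been chosen after their values were seen, except members of the lists given as examples of a list's count.

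Overlap of gene models was measured on GENCODE 29, in which 97.5% of the experiment 1 genes found there and 94.8% of those of experiment 2 had the same coordinates as in the tables. For 106 named genes, the share of 50-base windows of their transcripts that also occur in another gene was counted; 13 shared 10% or more. These are RIMBP3B, SRXN1, HIST1H2BK, HSPA1A, ALPP, RPL10A, ATF4, CD177, C15orf48, OSGIN1, NLGN4X, PRIM1 and KRT8, whose counts could have been split with those copies. Strand is not known, so counts may include reads of an overlapping gene on the other strand. Of such genes, 10% or more of the exonic bases of JUNB, ATF5, WIPI1, OVOL1, ALPP, C15orf48, IDI1, HMGCS1 and CLDN2 lie opposite such a gene. GC content and length came from the longest transcript of each gene and were known for 99.7% of the genes tested in S371A and 99.4% in S55A.

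Alternatives were RLE and upper quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, limma-trend on the deposited FPKM with pseudocounts of 1 and 0.1, each library left out, camera with an estimated correlation, fry, and a fit on all 12 libraries. Further settings were chosen after seeing the data: thinning every library to the lowest total, removing each library's trend on GC content and length with splines of 4 degrees of freedom, and leaving out genes that share exons or whose coordinates differ between the tables. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

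The procedure was tested on simulated counts with 200 changed genes per draw and 5 draws. With dispersions from the fitted trend, 3.9% of the calls were false for S371A over 16235 genes, 4.58% for S55A over 15521 genes and 5.07% for the difference over 16666 genes; with each gene's own estimated dispersion the shares were 9.8%, 10.8% and 6.1%. With trended dispersions, 80.0% of genes changed by a factor of 2 were recovered in the S371A design, 80.4% in the S55A design and 55.6% in the difference. In the list test, 3 of 3 lists shifted by a factor of 1.3 were recovered in each design and 0 of 25 others were called; those simulated genes varied independently of each other.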

Results

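The transcriptomes of SW1990 cells, a line from a spleen metastasis of pancreatic adenocarcinoma, were measured after 24 h without glucose. Per the labels, PHGDH, the first enzyme of serine synthesis, was expressed in its wild-type form or with the serine-to-alanine substitution S371A or S55A; whether the cells' own PHGDH was removed is not stated. The question of the series is which transcripts depend on these residues under nutrient stress, in the setting of a nuclear activity of PHGDH. Each mutant had 3 libraries and its own wild-type group of 3, WT-1 for S371A and WT-2 for S55A. No library from cells with glucose is part of the comparisons. Total counts per library ranged from 15932980 to 19240270 in WT-1, from 14102906 to 16182355 in S371A, from 13667033 to 17655119 in WT-2 and from 18262794 to 19100204 in S55A. A floor of 3 counts corresponded to between 0.156 and 0.22 CPM, which covers counting error only. Replicates of a group correlated with a Spearman coefficient between 0.988 and 0.992 across genes, and the biological coefficient of variation was 13.5% in experiment 1 and 13.8% in experiment 2.

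PHGDH itself was lower in both mutant groups. In experiment 1 (chromosome 1, 119648411 to 119744226, GRCh38) its level was 474 ± 19.6 CPM in WT-1 and 201 ± 20.7 in S371A, a log2 fold change of -1.24 ± 0.08 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000316). In experiment 2 it was 726 ± 17.5 CPM in WT-2 and 357 ± 9.13 in S55A, a log2 fold change of -1.03 ± 0.05 (adjusted p = 7.18e-05). Per library, PHGDH stood at 470, 495 and 456 CPM in WT-1, 196, 183 and 224 in S371A, 738, 706 and 734 in WT-2, and 364, 359 and 346 in S55A. The fall of PHGDH was not shown to differ between the mutants (adjusted p = 0.185). The counts do not tell forms of PHGDH apart. Every comparison therefore sets a mutant form, together with a lower PHGDH transcript level, against wild type.

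**Figure D1:**
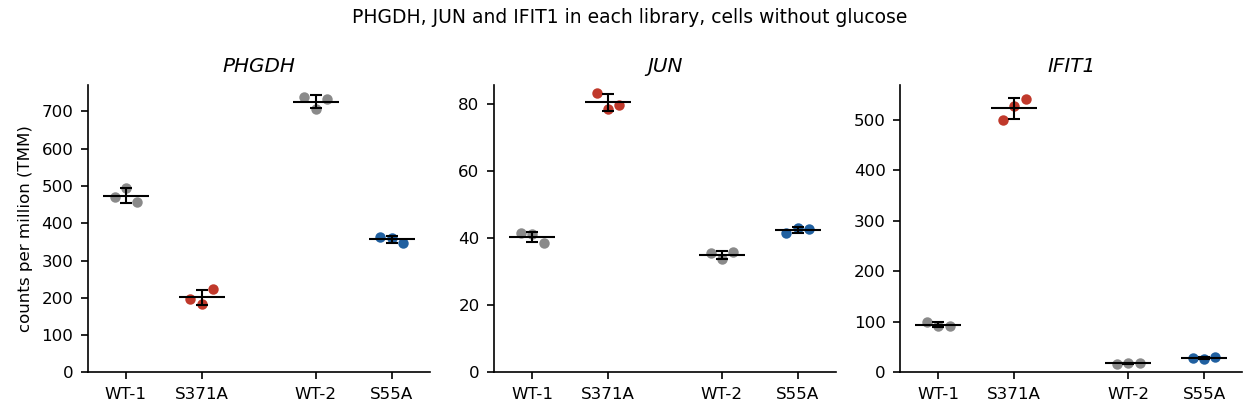
CPM of PHGDH, JUN and IFIT1 in each of the 12 libraries (points), with the mean and SD of each group of 3 (bars); both mutant groups lie below their wild type for PHGDH, and S371A stands at 80.6 CPM for JUN against 40.5 in WT-1. PHGDH is counted over different gene coordinates in the experiments.

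S371A cells had higher levels of interferon-response genes. IFIT3, an interferon-induced antiviral gene, stood at 30.1 ± 2.37 CPM in WT-1 and 227 ± 4.38 in S371A, a log2 fold change of 2.91 ± 0.06 (edgeR adjusted p = 3.13e-06). RSAD2, which encodes the antiviral enzyme viperin, rose by 2.88 ± 0.08, OASL by 2.78 ± 0.07, IFIT2 by 2.78 ± 0.07 and IFIT1 by 2.47 ± 0.05 on the log2 scale. Of the 34 measured genes of the interferon list, 23 rose and 1, IFI27, fell (25 and 2 adjusted over the list alone), with a median log2 fold change of 0.73 (camera adjusted p = 2.06e-17, adjusted p = 0.0679 with an estimated correlation). The chemokines CXCL10 (2.64 ± 0.12) and CXCL11 (2.50 ± 0.14) rose as well, from 2.49 and 2.21 CPM in WT-1. PHGDH was lower in the same libraries. The leukocyte markers summed to 12.8 ± 1.19 CPM in WT-1 and 15.3 ± 1.86 in S371A. No tested leukocyte marker passed the edgeR test, and 1 of them, CD68, had an unadjusted p under 0.05 (0.0358).

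JUN, the AP-1 transcription factor subunit, rose from 40.5 ± 1.53 CPM in WT-1 to 80.6 ± 2.48 in S371A, a log2 fold change of 0.99 ± 0.05 (edgeR adjusted p = 0.000123). Of the 15 measured AP-1 subunits, 6 rose and 0 fell (8 adjusted over the list alone), among them MAFF (0.75 ± 0.09) and JUNB (0.53 ± 0.06); the camera adjusted p was 0.000467, and the adjusted p = 0.0679 with an estimated correlation. Genes listed as JUN and AP-1 targets rose with them: 17 of 29 were higher and 1, HMGA1, was lower (18 and 4 adjusted over the list alone). Camera gave an adjusted p of 6.1e-08 (adjusted p = 0.0679 with an estimated correlation). Examples were PLAUR, the urokinase receptor (1.51 ± 0.10), EGR1, an immediate early transcription factor (1.22 ± 0.04), and EGFR (0.93 ± 0.05). In the MAPK immediate early list, 13 of 27 genes rose and 0 fell (15 and 2 adjusted over the list alone, camera adjusted p = 6.94e-08, adjusted p = 0.0679 with an estimated correlation), including EGR3 (1.93 ± 0.15) and ZFP36 (0.87 ± 0.06). Lists can share members, as this list and the JUN and AP-1 targets share DUSP5. Their calls, here and in S55A, are therefore not separate support. In the NF-kB and cytokine list, 10 of 18 rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 4.19e-08, adjusted p = 0.0679 with an estimated correlation), including TNFAIP3, a feedback inhibitor of NF-kB signalling (1.28 ± 0.12), and NFKBIZ (0.89 ± 0.07).

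Further lists were called in S371A. For G2/M genes, 12 of 30 rose and 0 fell (21 adjusted over the list alone), with a median of 0.25, among them CDC20 (0.43 ± 0.05), CENPF (0.41 ± 0.06) and TPX2 (0.37 ± 0.05); the camera adjusted p was 1.43e-09 (adjusted p = 0.15 with an estimated correlation). Cytosolic ribosomal protein genes went the other way, with 9 of 50 lower and 0 higher (17 lower adjusted over the list alone) and a median of -0.18 (camera adjusted p = 2.36e-06, adjusted p = 0.18 with an estimated correlation); RPL22 changed by -0.40 ± 0.05 and RPL5 by -0.33 ± 0.04. Among NRF2 targets, 10 of 24 rose and 0 fell (10 adjusted over the list alone, camera adjusted p = 8.93e-05, adjusted p = 0.0679 with an estimated correlation), including HMOX1, heme oxygenase (1.06 ± 0.11), and OSGIN1 (1.06 ± 0.11). Of 19 heat shock genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.000899, adjusted p = 0.0679 with an estimated correlation), including BAG3 (0.57 ± 0.07) and DNAJB4 (0.66 ± 0.08); HSPA1A (0.60 ± 0.06) shares 71.3% of its windows with HSPA1B, so its own value is uncertain. Of 6 histone genes, 4 rose (5 adjusted over the list alone), with a median of 0.69. The camera adjusted p was 0.00356 (adjusted p = 0.104 with an estimated correlation). Of 20 mesenchymal and matrix genes, 6 rose and 2 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.156 with an estimated correlation), with rises of CYR61 (1.49 ± 0.12), LAMA3 (1.33 ± 0.09) and THBS1 (0.50 ± 0.04).

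Among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap, the largest falls in S371A were those of SLC7A2, a cationic amino acid transporter (-2.14 ± 0.32), MAP3K13, a kinase of the JNK pathway (-1.88 ± 0.11), and EEF1A2, a translation elongation factor (-1.63 ± 0.11). ALPI, intestinal alkaline phosphatase (-1.47 ± 0.12), TNNI2 (-1.41 ± 0.10), RASIP1 (-1.35 ± 0.09), IZUMO1 (-1.33 ± 0.10) and NLGN4X (-1.31 ± 0.13) followed. SLC7A2 missed the threshold without S371A replicate 3 (edgeR adjusted p = 0.0628), and the rise of ITGB8 (2.36 ± 0.34) did so without WT-1 replicate 1 (adjusted p = 0.053). Of 18 serine synthesis and one-carbon genes other than PHGDH, 4 fell and 0 rose (6 and 2 adjusted over the list alone), among them ALDH1L1, MAT2A and AHCY, and the list was not called (camera adjusted p = 0.0835). PARP1 stood at 384 ± 7.4 CPM in WT-1 and 362 ± 12.6 in S371A (adjusted p = 0.231), and ATF4 at 882 ± 42.9 and 858 ± 38.3 (adjusted p = 0.672).

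In total, 2042 of 16235 tested genes differed between S371A and WT-1, 1144 higher and 898 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and 282 of them by a log2 fold change of at least 1. The balance turned with upper quartile factors (990 higher and 1078 lower), with no filter (945 and 1038) and on FPKM (763 and 783 with a pseudocount of 1). The groups did not overlap for 36.5% of tested genes, where chance gives 10%. The count fell to 997, 917 and 927 without WT-1 replicate 1, 2 or 3, and to 1191 and 1118 without S371A replicate 2 or 3. The other 17 pathway lists were not called, and for the epithelial list (median 0.09, test upward) and the tRNA synthetase list (mean 0.02, test upward) the mean and the median differed in sign. Among the markers of other cell types, the fibroblast marker PDGFRB was lower and the pancreatic marker BHLHA15 was higher. The fibroblast list summed to 90.6 ± 2.83 CPM in WT-1 and 76.6 ± 3.34 in S371A, and the pancreatic list to 37.0 ± 2.92 and 42.5 ± 0.85. No tested endothelial or hepatocyte marker passed, with sums of 14.9 ± 1.41 and 13.5 ± 0.467 CPM for the former and 5.55 ± 0.308 and 6.36 ± 0.302 for the latter.

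S55A cells had lower levels of DNA replication genes and higher levels of epithelial differentiation genes. Of 34 measured S phase genes, 19 fell and 0 rose (21 adjusted over the list alone), with a median log2 fold change of -0.42 (camera adjusted p = 8.41e-11, adjusted p = 0.211 with an estimated correlation). CLSPN, a replication checkpoint adaptor, changed by -0.73 ± 0.09, PRIM1, the primase subunit, by -0.64 ± 0.09, and UNG, uracil DNA glycosylase, by -0.59 ± 0.08; PCNA, MCM3, MCM4 and MCM7 were among the other members that fell. Of 30 G2/M genes, 8 fell and 0 rose (9 adjusted over the list alone, median -0.16). For this list the camera adjusted p was 0.000551 (adjusted p = 0.337 with an estimated correlation). CENPE, the kinetochore motor, fell from 79.9 ± 0.58 CPM in WT-2 to 20.8 ± 0.429 in S55A, a log2 fold change of -1.94 ± 0.07 (edgeR adjusted p = 8.69e-06), and ASPM changed by -0.89 ± 0.09. Replication-dependent histone genes rose in the same cells: 5 of 6 were higher (6 adjusted over the list alone, median 1.08, camera adjusted p = 0.000254, adjusted p = 0.186 with an estimated correlation), including HIST2H2BE (1.18 ± 0.21). PHGDH was lower in these libraries too.

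KRT20, a keratin of intestinal epithelium, rose from 29.6 ± 2.54 CPM in WT-2 to 229 ± 24.8 in S55A, a log2 fold change of 2.95 ± 0.10 (edgeR adjusted p = 8.69e-06). Of 30 epithelial junction and differentiation genes, 17 rose and 0 fell (24 adjusted over the list alone, median 0.53). By camera the adjusted p was 6.34e-10 (adjusted p = 0.165 with an estimated correlation). OVOL1, an epithelial transcription factor, rose by 1.58 ± 0.15, and KRT8 by 0.75 ± 0.06, from 1152 ± 59.2 to 1938 ± 61.7 CPM. CLDN1, CLDN3 and OCLN, which encode junction proteins, were also higher. CLDN2, another claudin gene but outside the list, fell (-1.86 ± 0.14). Other large rises were those of C15orf48 (3.26 ± 0.29), CD74, the MHC class II invariant chain (2.93 ± 0.23), CLIC5 (2.48 ± 0.19), PHGR1 (2.33 ± 0.26), NMNAT2, an enzyme of NAD synthesis (2.30 ± 0.16), and HMCN2 (2.28 ± 0.22). RIMBP3B had 0 counts in all 3 WT-2 libraries and 12.3 ± 1.08 CPM in S55A, at least 66.0-fold higher against a floor of 3 counts per library, but 98.2% of its windows also occur in other genes, chiefly RIMBP3C, so its reads could not be assigned. Within the same limits on symbol, mean level and overlap, the largest falls were those of A2ML1, a protease inhibitor (-2.85 ± 0.16), ALPP, placental alkaline phosphatase (-2.17 ± 0.09), CENPE, CCDC88A (-1.88 ± 0.15), CLDN2 (-1.86 ± 0.14), ABCC2 (-1.76 ± 0.14), CEP290, a ciliary protein (-1.60 ± 0.07), and BTBD3 (-1.59 ± 0.12).

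Interferon-response genes rose in S55A as well. Of 30 measured members, 17 rose and 0 fell (24 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.58e-09, adjusted p = 0.0536 with an estimated correlation), including ISG15 (0.65 ± 0.08), IFIT1 (0.65 ± 0.09) and OAS3 (0.54 ± 0.06). IFIT1 went from 18.3 ± 1.07 CPM in WT-2 to 28.7 ± 1.48 in S55A. PHGDH was lower here as in S371A, and the leukocyte list summed to 12.9 ± 1.72 CPM in WT-2 and 13.4 ± 2.15 in S55A. JUN stood at 35.1 ± 1.21 CPM in WT-2 and 42.5 ± 0.84 in S55A, a log2 fold change of 0.28 ± 0.07 (edgeR adjusted p = 0.0345) that missed the threshold when any 1 of the 6 libraries was left out (adjusted p between 0.0551 and 0.101). Of 13 AP-1 subunits, 6 rose and 0 fell (7 adjusted over the list alone, camera adjusted p = 0.0056, adjusted p = 0.165 with an estimated correlation), with JUNB at 0.78 ± 0.09. The MAPK immediate early list had 10 of 25 higher and 0 lower (13 adjusted over the list alone, camera adjusted p = 0.000183, adjusted p = 0.132 with an estimated correlation), including DUSP5 (1.09 ± 0.14), ETV5 (0.68 ± 0.09) and KLF10 (0.62 ± 0.07).

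Stress lists were called in S55A too. Of 21 hypoxia genes, 6 rose and 0 fell (10 adjusted over the list alone, camera adjusted p = 0.00126, adjusted p = 0.278 with an estimated correlation), with NDRG1 at 0.94 ± 0.11 and P4HA2 at 0.67 ± 0.08. Of 27 ATF4 and integrated stress response targets, 8 rose and 1 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.176 with an estimated correlation); ADM2 (0.76 ± 0.06) and PPP1R15A (0.65 ± 0.06) rose and ATF5 changed by -0.73 ± 0.08. ATF4 itself stood at 964 ± 19.3 CPM in WT-2 and 1062 ± 30.5 in S55A (edgeR adjusted p = 0.107), and PARP1 at 358 ± 16.1 and 311 ± 32.1 (adjusted p = 0.13). Of 24 unfolded protein response genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.165 with an estimated correlation), including DNAJB9 (0.59 ± 0.06) and SELENOS (0.33 ± 0.06). The autophagy and lysosome list had 8 of 32 higher and 1 lower (12 and 4 adjusted over the list alone, camera adjusted p = 0.0247, adjusted p = 0.186 with an estimated correlation), with NEU1 at 0.66 ± 0.09 and WIPI1 at 0.49 ± 0.09. The NF-kB list had 5 of 14 higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.165 with an estimated correlation), including LIF (0.71 ± 0.10) and LCN2 (0.61 ± 0.07).

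A further 3 lists were called in S55A, and each lost its call when 1 library was left out. Of 28 JUN and AP-1 targets, 8 rose and 2, AREG (-0.76 ± 0.10) and EREG, fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0247, adjusted p = 0.211 with an estimated correlation; 0.0535 without WT-2 replicate 2), and TGFB1 rose by 0.64 ± 0.08. Of 28 apoptosis regulators, 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0252, adjusted p = 0.176 with an estimated correlation; 0.077 without WT-2 replicate 3); BIK, which promotes cell death, rose by 0.73 ± 0.13, and BCL2, which opposes it, changed by -1.48 ± 0.21. Of 24 cholesterol synthesis genes, 4 fell and 0 rose (5 adjusted over the list alone, camera adjusted p = 0.0114, adjusted p = 0.53 with an estimated correlation; 0.209 without S55A replicate 3), including IDI1 (-0.45 ± 0.07). The serine synthesis and one-carbon list was not called (camera adjusted p = 0.16), with 1 of 18 higher and 3 lower (2 and 5 adjusted over the list alone).

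In total, 2488 of 15521 tested genes differed between S55A and WT-2, 1392 higher and 1096 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 383 of them by a log2 fold change of at least 1. With upper quartile factors 1221 were higher and 1258 lower. The groups did not overlap for 38.2% of tested genes, where chance gives 10%. The count fell to 1344 and 1485 without WT-2 replicate 1 or 3, and to 1416 and 1372 without S55A replicate 1 or 2. The other 13 pathway lists were not called, and the NRF2 list had a median of -0.03 with an upward test. Among the markers of other cell types, the hepatocyte marker SERPINA1 and the pancreatic marker BHLHA15 were higher, and ALB and PRSS1 were lower. No tested fibroblast, leukocyte or endothelial marker passed. The sums in WT-2 and S55A were 58.6 ± 1.63 and 61.3 ± 9.78 CPM for fibroblast, 14.9 ± 1.81 and 16.9 ± 1.28 for endothelial, 4.79 ± 1.05 and 3.99 ± 0.689 for hepatocyte and 31.7 ± 2.43 and 42.5 ± 1.73 for pancreatic markers.

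**Figure D2:**
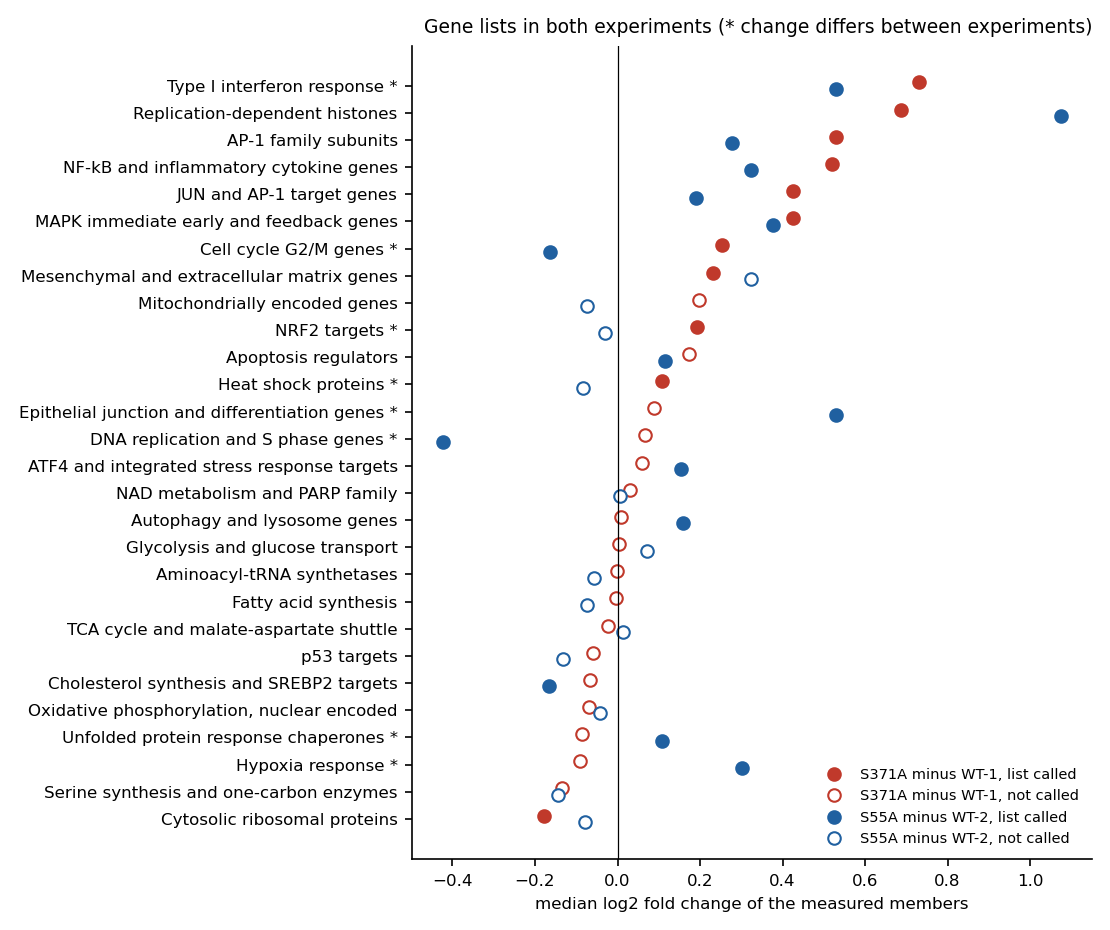
Median log2 fold change of the measured members of 28 gene lists (horizontal axis) in S371A against WT-1 (red) and S55A against WT-2 (blue); filled points mark lists called by camera with its preset correlation, and an asterisk marks lists whose change differed between the experiments by the same test. The interferon list lies at 0.73 in S371A (34 members) and 0.53 in S55A (30 members), or at 1.21 and 0.53 over the 30 members tested in both; the S phase list lies at 0.07 and -0.42.

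By camera with its preset correlation, the mutant effects differed for the cell cycle, epithelial and interferon genes. Taking the change in S371A minus that in S55A, 20 of 34 S phase genes had a higher difference and 0 a lower one (28 adjusted over the list alone, median 0.49, camera adjusted p = 1.6e-13, adjusted p = 0.0777 with an estimated correlation), and so did 17 of 30 G2/M genes against 0 (21 adjusted over the list alone, median 0.46). Tested with camera, the list had an adjusted p of 2.15e-12 (adjusted p = 0.0636 with an estimated correlation). For epithelial genes 12 of 30 had a lower difference and 1 a higher one (17 and 1 adjusted over the list alone, median -0.42). Camera gave an adjusted p of 1.61e-07 (adjusted p = 0.0536 with an estimated correlation). For interferon genes 13 of 34 had a higher difference and 1 a lower one (14 and 2 adjusted over the list alone, median 0.49, camera adjusted p = 1.23e-06), and this call held with an estimated correlation (adjusted p = 0.0142). The wild-type groups stood at different levels for some of these genes, a comparison that was not tested; for example, IFIT1 was at 94.6 ± 4.38 CPM in WT-1 and 18.3 ± 1.07 in WT-2. The difference in JUN was 0.72 on the log2 scale (edgeR adjusted p = 0.000199).

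Stress lists also differed in this contrast, in which mutant and experiment are not separable. NRF2 targets stood higher in S371A relative to S55A, with 9 of 24 higher and 1 lower (14 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 1.47e-05), as did heat shock genes, with 8 of 19 higher and 0 lower (9 adjusted over the list alone, median 0.20, camera adjusted p = 0.000506). Unfolded protein response genes stood lower, with 6 of 24 lower and 0 higher (11 adjusted over the list alone, median -0.20, camera adjusted p = 9.22e-05). These 3 calls also held with an estimated correlation (adjusted p = 0.0142, 0.0474 and 0.0142); with the interferon list they are the 4 calls that did, against 0 in S371A alone and 0 in S55A alone. Hypoxia genes stood lower too, with 4 of 21 lower and 1 higher (6 and 1 adjusted over the list alone, median -0.33). The camera adjusted p was 0.000988 (adjusted p = 0.19 with an estimated correlation). For 5 of the lists that were not called for the difference, the median, the mean and the test did not all share a sign. These were the AP-1 subunits (median -0.17, mean 0.13, test upward), serine and one-carbon enzymes (median 0.12, mean -0.01, test upward), NAD and PARP genes (median 0.06, mean -0.08, test downward), p53 targets (median 0.01, mean 0.01, test downward) and apoptosis regulators (median -0.02, mean 0.14, test upward).

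**Figure D3:**
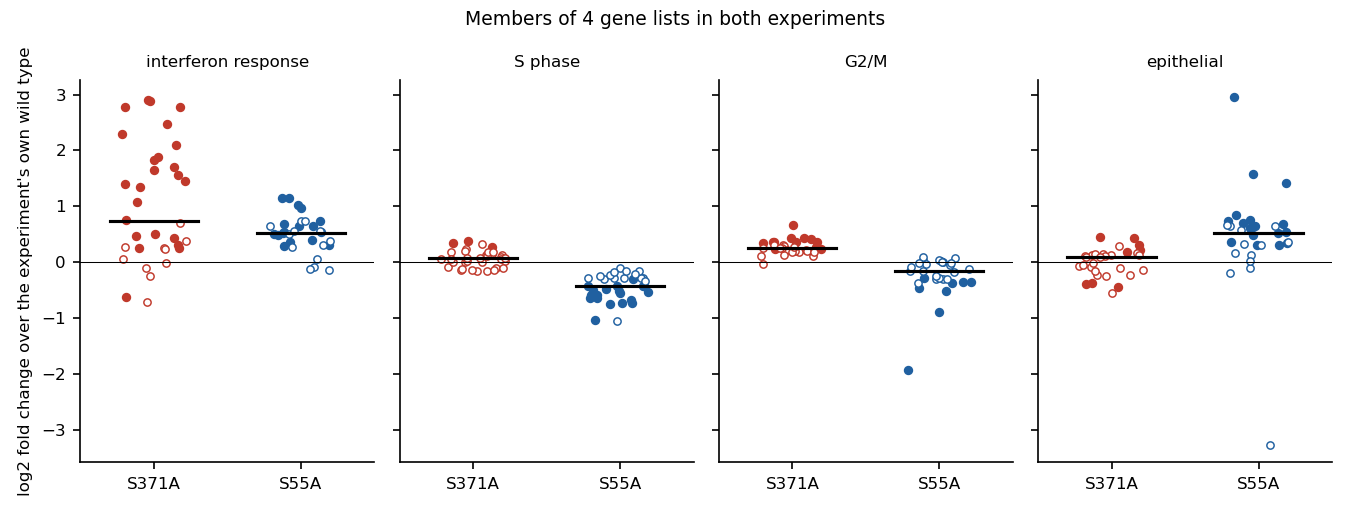
Log2 fold change of each measured member (points) of 4 gene lists in S371A against WT-1 (red) and S55A against WT-2 (blue), with the median (bar); filled points passed the edgeR test. S phase members lie around 0.07 in S371A and -0.42 in S55A.

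Among single genes, NRP1, a semaphorin and VEGF co-receptor, rose in S371A (1.49 ± 0.10) and fell in S55A (-1.20 ± 0.16), a difference of 2.70 ± 0.17 (edgeR adjusted p = 3.67e-06). CENPE rose in S371A (0.67 ± 0.09) and fell in S55A, a difference of 2.61 ± 0.11 (adjusted p = 3.15e-07). For KRT17 the difference was 2.37 ± 0.24 and for RSAD2 2.32 ± 0.22. In the other direction KRT20 fell in S371A (-0.39 ± 0.05) and rose in S55A, a difference of -3.34 ± 0.12 (adjusted p = 5.64e-08). The differences of PHGR1 (-2.87 ± 0.30), S100P (-2.39 ± 0.12) and CD177 (-2.37 ± 0.11) had the same sign. Genes with a mean under 5 CPM over the 12 libraries or with a clone-based name were not ranked. S100P ranged from 46.5 to 54.96 CPM over the WT-1 libraries, 12.9 to 16.3 in WT-2 and 47.7 to 48.7 in S55A. CD177 ranged from 44.4 to 48.4 CPM in WT-1, 16.3 to 17.7 in WT-2 and 50.02 to 54.8 in S55A. KRT20 ranged from 84.7 to 89.6 CPM in WT-1 and from 28.2 to 33.1 in WT-2. KRT17 and RSAD2 were also higher in WT-1, NRP1 was lower there, and the ranges of CENPE and PHGR1 overlapped. The wild-type groups were not tested against each other for these genes. ZNF664 (3.81 ± 0.55) and TGOLN2 (-3.01 ± 0.80) also passed, but their libraries varied within groups. ZNF664 stood at 93.6, 91.1 and 269 CPM in the S55A libraries and TGOLN2 at 179, 46.4 and 181 CPM in WT-1. ZNF664 also ranged from 148 to 162 CPM in WT-1 and from 622 to 665 in WT-2. Leaving out any 1 library other than WT-1 replicate 2 or S371A replicate 2 ended the call of the TGOLN2, difference of S371A and S55A (adjusted p between 0.0578 and 0.0958). In all, 2087 of 16666 genes changed differently, 1071 with a higher and 1016 with a lower difference, a balance that turned with DESeq2 (1113 and 1217) and with upper quartile factors (1026 and 1050).

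The experiments also shared part of their changes, with no library in common. Of 15126 genes tested in both, 314 were higher in both mutants, where 98.9 would be shared by independent lists (odds ratio 4.97, Fisher's exact test, two-sided, adjusted p = 7.66e-86), and 139 were lower in both, against 62.3 (odds ratio 2.68, adjusted p = 1.32e-19). Shared rises included IFIT1, IFIT2, IFIT3, OASL, PLAUR, CD74 and CLIC5; shared falls included A2ML1, RASIP1, IZUMO1 and TNNI2 besides PHGDH. Opposite calls numbered 70 for higher in S371A and lower in S55A, against 76.7, and 67 for the reverse, against 80.3. The log2 fold changes correlated with a Spearman coefficient of 0.16 across genes, which are not independent replicates. The count of genes called in both experiments in the same direction, 453, fell to 281, 263 and 258 without WT-1 replicate 1, 2 or 3, to 280 without S371A replicate 3, to 286 without WT-2 replicate 1 and to 294 without S55A replicate 2.

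**Figure D4:**
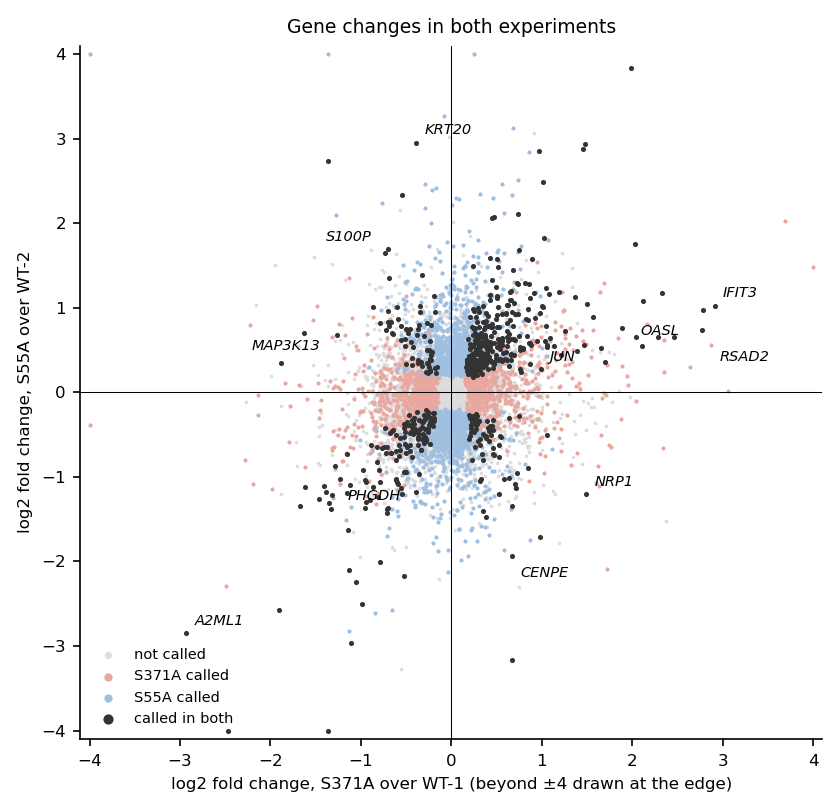
Log2 fold change of each gene tested in both experiments in S371A against WT-1 (horizontal axis) and in S55A against WT-2 (vertical axis); black points were called in both, coloured points in either, grey points in neither, and values beyond 4 are drawn at the edge. Most of the black points lie in the quadrants of equal direction, 314 higher and 139 lower in both.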

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

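The thinning of the libraries, the removal of the GC and length trend, the comparison with the drop of PHGDH and the PTPRC count were tests chosen after the results were seen. Each value that follows is the log2 fold change of S371A against WT-1 minus that of S55A against WT-2, and each stands out because the test of this difference passed edgeR's adjusted threshold (genes) or camera's (lists). Genes with a higher value in S371A were ZNF664 3.81, NRP1 2.70, CENPE 2.61, KRT17 2.37, CXCL10 2.35, RSAD2 2.32, IFIT2 2.05, BTBD3 1.97, ABCC2 1.92, IFIT3 1.90, CEP290 1.84, CLDN2 1.83, IFIT1 1.82 and OASL 1.82. Smaller positive differences were EGR3 1.77, CCDC88A 1.73, ALPP 1.65, ISG15 1.64, AREG 1.29, BCL2 1.28, NFKBIZ 1.24, ASPM 1.21, LAMA3 1.17, CLSPN 1.07, TNFAIP3 1.05, HMGCS1 1.04, CYR61 0.93 and CENPF 0.87. The remaining positive ones were EGR1 0.78, EGFR 0.76, DNAJB4 0.75, UNG 0.74, JUN 0.72, OSGIN1 0.71, ZFP36 0.54, SRXN1 0.54, HMOX1 0.53, PRIM1 0.50, CDC20 0.48, SOD2 0.47, IDI1 0.39 and TPX2 0.35. Genes with a lower value in S371A were C15orf48 -3.34, KRT20 -3.34, TGOLN2 -3.01, PHGR1 -2.87, S100P -2.39, CD177 -2.37, EEF1A2 -2.32, NMNAT2 -2.25, MAP3K13 -2.23, HMCN2 -2.19, SLC7A2 -2.10 and ALPI -1.58. Smaller negative differences were CLIC5 -1.47, CD74 -1.45, NDRG1 -1.26, HIST2H2BE -1.20, OVOL1 -1.15, THBS1 -1.07, LCN2 -0.99, P4HA2 -0.96, BIK -0.77, TGFB1 -0.76, ADM2 -0.66 and DUSP5 -0.66. The remaining negative ones were WIPI1 -0.58, KLF10 -0.35, RPL10A -0.28 and DNAJB9 -0.25. Among gene lists, the median difference was 0.49 for S phase genes, 0.49 for interferon-response genes, 0.46 for G2/M genes, 0.31 for NRF2 targets and 0.20 for heat shock genes. It was -0.42 for epithelial genes, -0.33 for hypoxia genes and -0.20 for unfolded protein response genes.

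Other splits of the libraries were counted for each comparison. The 6 libraries of an experiment allow 10 splits, too few for a share under 0.05. In S371A, 1 of 10 splits, the real one, gave 2042 genes and the highest other gave 8, and 1 of 10 gave 11 lists against 6 for the highest other. In S55A, 1 of 10 gave 2488 genes against 5, and 1 of 10 gave 15 lists against 8. The other splits called 1 to 6 lists in S371A (median 4) and 5 to 8 in S55A (median 6). Camera with its preset correlation thus called lists without the real grouping as well. For the difference, 1 of 100 splits gave 2087 genes, the real one, and the highest other gave 854. The 82 splits that mixed both experiments called 6 genes at most, since mixing puts the mutant effects into the spread within groups. Those that kept experiment 2 called 429 to 854 and those that kept experiment 1 called 68 to 205. Such splits stand for a mutant without effect, not for equal effects, so they cannot decide whether the effects differ by chance. As for the count of lists, 38 of 100 splits called at least the 8 lists of the real one, and the highest other called 17. Of these, 10 of the 11 splits that kept the groups of experiment 2 and 6 of the 6 that kept those of experiment 1 called as many lists, as did 21 of the 82 that mixed both. The number of lists called by camera with its preset correlation is therefore no evidence of a difference by itself.

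Interferon-response genes rose in S371A by a median of 0.73, and RNA from leukocytes in those libraries would bring other leukocyte transcripts, whose summed level was 2.47 CPM higher than in WT-1. This exceeded its spread, so the bound set beforehand against this source was not fully met, but that bound counted CORO1A, already at 10.4 ± 0.873 CPM in WT-1 (12.4 ± 1.85 in S371A), and without it the rise was 0.447 CPM. No leukocyte marker was called higher, 7 of 15 had 0 counts in all S371A libraries, PTPRC among them, while the interferon list rose from 1548 ± 28.9 to 4077 ± 45.7 CPM in sum, which argues against this source. Thinning every library to the lowest total left the median at 0.74 (camera adjusted p = 1.3e-17), so the call did not need the unequal totals. Thinning keeps the expected share of each gene in its library, so it could hardly move this median. It cannot decide whether depth played a part in another way. The lower PHGDH transcript cannot be told apart from the substitution, because both mutant groups carry it: over the 30 interferon genes tested in both experiments, the median in S55A was 0.438 of that in S371A (0.53 against 1.21), where the PHGDH change was 0.831 of that in S371A.

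Cell cycle genes moved apart, with S phase genes lower in S55A and a median difference of 0.49. Thinning left that median at 0.47 (camera adjusted p = 9.13e-13), which, as for the interferon list, it could hardly have moved. Removal of the GC and length trend left the median at 0.46 (camera adjusted p = 1.08e-13), which argues against that trend as the whole cause. Wild-type cells in different growth states were predicted to put WT-2 above WT-1 on the S phase list. Over 33 of its genes with the same coordinates in both tables, however, WT-2 minus WT-1 was 0.010 and S55A minus S371A -0.40. These values cover that list only and do not exclude other differences between the wild-type cells. MYC stood at 137 ± 6.28 CPM in WT-1 and 7.71 ± 2.73 in WT-2. Over all genes with the same coordinates, WT-2 minus WT-1 had an SD of 0.83 in log2 CPM. The S55A substitution and the lower PHGDH level that goes with it were not separated by the design. Cell cycle phases were not measured, so what lowered the S phase genes stays open. Replication-dependent histone genes rose in the same S55A libraries (median 1.08 over 6 measured members), but at low levels. HIST1H2BD reached 8.27 CPM in S55A replicate 3 and HIST2H2BE 4.64 CPM in S55A replicate 2. Whether this rise bears on replication was not tested.

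Some genes swung widely between replicates of 1 group. Among the 1% of genes with the largest spread in experiment 1, 51 of 120 (42.5%) shared at least 10% of their exonic bases with another gene on the same strand, 5.74 times the share of the other genes (7.41%). In experiment 2 it was 39 of 115 (33.9%), 4.52 times that of the others (7.5%). Read-through models such as ISY1-RAB43, SENP3-EIF4A1 and BIVM-ERCC5 were among them. Reads assigned to either of the overlapping models from library to library would give such swings. Most of the 1% did not reach this overlap, however, and some shared no exonic base on the same strand. Examples are AHNAK (59.6 to 1254 CPM over the libraries of experiment 1) and PRNP (23.6 to 144 CPM in experiment 2). Shared exons leave the swings of such genes unexplained. Of the 1% with the largest spread, 1 was called in S371A and 0 in S55A by edgeR, and no biological explanation was tested.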

How the results depend on the processing

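Thinning, removal of the GC and length trend and the settings without overlapping or moved gene models were tests chosen after the data were seen, and the others were planned. No called gene was called in the opposite direction under another setting run, and no called list or named gene changed direction. Lists that were not called did: with the replicate block the tests of the fatty acid list in S371A and of the NRF2 list in S55A turned round, and the medians of some others changed sign in other settings or with a library left out. The balance of higher and lower calls also depended on the setting. More genes were lower than higher in S371A with upper quartile factors (990 higher and 1078 lower), no filter (945 and 1038) and FPKM (763 and 783, or 760 and 769 with a pseudocount of 0.1), and in S55A with upper quartile factors (1221 and 1258). For the difference this held with RLE (1028 and 1030) or upper quartile factors (1026 and 1050), DESeq2 (1113 and 1217), FPKM (904 and 912, or 871 and 897), GC and length removal (1052 and 1106) and 10 of the 12 libraries left out in turn. The count of genes was within 1.5 times of the original with RLE or upper quartile factors, DESeq2, limma-voom, no filter or a CPM filter, FPKM, thinning, GC and length removal, without genes that share exons, without genes whose coordinates differ (difference only) and, for the mutants, with all 12 libraries in 1 fit. It ranged over these from 1529 to 2148 in S371A, from 1890 to 3611 in S55A and from 1707 to 2330 for the difference. The fall of PHGDH kept its direction and its call throughout.

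Requiring an absolute log2 fold change of at least 1 left 282 genes in S371A, 383 in S55A, 499 for the difference and 35 called in both experiments, a stricter count by construction. On FPKM these counts were lower still, 67 in S371A, 48 in S55A and 112 for the difference with a pseudocount of 1, and 134, 151 and 266 with 0.1. With the replicate number as a block the counts were 784, 1632, 1098 and 202. The labels give no sign that numbers pair the libraries, and same-numbered libraries did not deviate together (correlations of -0.0375, -0.0851 and -0.0110 in S371A, and -0.00289, -0.0479 and -0.0509 in S55A). A block leaves fewer degrees of freedom by construction, and no other cause of the lower counts was tested. With an estimated correlation, camera called 0 lists in S371A, 0 in S55A and 4 for the difference. Fry, which does not compare a list with other genes, called 18 lists in S371A and 13 for the difference.

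Leaving out each library in turn gave 917 to 1576 genes in S371A, 1344 to 2491 in S55A, 1407 to 2257 for the difference and 258 to 462 genes called in both experiments, against 453. Fewer libraries lower the power by construction; why some libraries cost more calls than others was not tested. Lists called ranged from 11 to 13, 15 to 16 and 8 to 10, and the log2 fold change of PHGDH from -1.32 to -1.17 in S371A, with -1.04 as the lowest in S55A. Among single lists, 31 values in the other settings lost the call, 30 of them with an estimated correlation, and 24 gained it. With a library left out, 3 lost it and 23 gained it. Among single named genes 13 values lost the call in the other settings and 54 with a library left out. Thinning to the lowest total left 1875 calls in S371A and 2394 in S55A.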

Other observations

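The genes in this part were chosen after their values were seen, and no explanation was tested. Interferon genes themselves were low. IFNL1, a type III interferon, had 93 counts over the WT-1 libraries and 412 over S371A, 1.75 ± 0.227 and 8.90 ± 1.47 CPM, a log2 fold change of 2.35 ± 0.18 (edgeR adjusted p = 0.000692). IFNB1 had 37 and 72 counts, a log2 fold change of 1.18 ± 0.33 (adjusted p = 0.0603). In experiment 2 these genes were below the filter, with 8 and 20 counts for IFNL1 and 5 and 5 for IFNB1. The RNA sensors DDX58 (1.70 ± 0.06) and IFIH1 (1.39 ± 0.07) rose in S371A. Both also rose in S55A, by less (0.36 ± 0.09, edgeR adjusted p = 0.03, and 0.49 ± 0.11, adjusted p = 0.0215).

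The wild-type groups of the experiments differed in level. Over genes with the same coordinates in both tables, WT-2 minus WT-1 had an SD of 0.83 in log2 CPM. That SD across genes also holds the spread between libraries. MYC, at the same coordinates in both tables, stood at 137 ± 6.28 CPM in WT-1 and 105 ± 16.5 in S371A (edgeR adjusted p = 0.077), but at 7.71 ± 2.73 in WT-2 and 10.2 ± 1.92 in S55A. PVT1, the neighbouring gene, stood at 12.1 ± 0.734 CPM in WT-1 and 12.9 ± 2.15 in WT-2. KRT20 stood at 88.8 ± 2.48 CPM in WT-1 and 29.6 ± 2.54 in WT-2. Several interferon-response genes stood higher in WT-1 than in WT-2. IFIT1 was at 94.6 ± 4.38 and 18.3 ± 1.07 CPM, DDX58 at 77.0 ± 5.14 and 34.0 ± 2.95, and IFIH1 at 49.1 ± 2.50 and 17.0 ± 0.613. ISG15 was at 67.9 ± 3.42 and 36.3 ± 1.88 CPM, and OAS3 at 164 ± 5.02 and 65.98 ± 1.52. RSAD2, scaled over all 12 libraries, ranged from 12.9 to 15.7 CPM in WT-1 and from 3.16 to 4.05 in WT-2. Others did not stand higher, IRF7 being at 22.9 ± 1.76 and 22.5 ± 0.528 CPM and STAT2 at 89.02 and 91.2. The list as a whole was not tested between the wild-type groups. For IFIT1, DDX58, IFIH1, ISG15, OAS3 and RSAD2 the mutant effects start from unequal levels. Except for RSAD2, the levels of these single genes were scaled within separate tables. The difference between wild-type groups was not tested.

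The clone-named AC087190.3, whose exons lie within C16orf72, went from 1.68 ± 0.368 CPM in WT-1 to 125 ± 5.36 in S371A, while C16orf72 went from 212 ± 3.77 to 118 ± 0.621. In experiment 2, AC087190.3 varied within WT-2 (40.5 ± 68.0 CPM). RIMBP3B, absent from WT-2, stood at 6.82 ± 5.92 CPM in WT-1 and 2.73 ± 4.73 in S371A, so its counts varied between replicates of 1 group there.

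Changes shared by both mutants included APOL6 (2.04 in S371A and 1.75 in S55A on the log2 scale), ICAM2 (1.99 and 3.84), REG4 (1.46 and 2.88), GBP3 (1.01 and 1.02), IGF2 (-1.13 and -2.10), CDX1 (-1.62 and -1.11) and A2ML1 (-2.93 and -2.85).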
